A study of Mangifera indica with 4 samples.

How the data were processed

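RNA was taken from fruit mesocarp of Mangifera indica cultivar Alphonso with a column kit and made into Illumina libraries, per the labels' protocols. The 4 libraries cover 2 tissue conditions (healthy and spongy) and 2 stages (5 and 10 days after harvest), with 1 library per group, per the labels. The submitters' processing notes name CASAVA 1.8.2, Bowtie2 2.2.3 and DESeq2, whose version is not given in the sources used here. The transcript assembly, the read counter, any filter and the model formula are not given in the sources used here.

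The files hold 4 tables of the authors' own comparisons over the same 30582 transcripts, with no column for a single library. The deposited mean normalized count is a signal averaged over all 4 libraries after division by size factors, and it was the same in every table. The log2 fold change and its standard error on the log2 scale were computed by the authors with DESeq2, per the file headers and the submitters' processing notes. The deposited test statistic is a score, the log2 fold change divided by its standard error. The p-value and the adjusted p-value are those of the authors' test, per the file headers. The median standard error of the log2 fold change in the authors' deposited table was 0.78 for healthy over spongy fruit at 5 days, 0.82 at 10 days, 0.82 for the stages of healthy fruit and 0.79 for those of spongy fruit.

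The level of each transcript in each library was worked out from the deposited mean and the deposited fold changes, since 3 fold changes and 1 mean fix 4 values. Around the loop of the 4 tables the fold changes closed to within 4.88e-14. The values of each library came out as whole multiples of 1 step, the inverse of its size factor. Of 103991 values under 1000 reads, 99.98% were within 0.05 of a whole number when each fold change was read as the first-named group of its table over the second. In the opposite reading 10.0% were whole, so the direction of the fold changes was taken from the first. Of the 17581 values of 1000 reads or more, 95.0% were within 0.05 of a whole number. Which group is healthy and which is spongy rests on the names of the tables. Values under 0.35 read were set to 0, and the others were scaled back to the deposited mean. The size factors were 1.84 in healthy fruit at 5 days, 0.389 in healthy fruit at 10 days, 1.27 in spongy fruit at 5 days and 1.11 in spongy fruit at 10 days. Transcripts with 0 reads numbered 149, 426, 83 and 98 in the same order, and 5 had 0 in every library.

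For each comparison, transcripts with a mean normalized level of at least 10 over its 2 libraries were compared. The log2 ratio was taken after adding 1 to each level, which understates the difference of low transcripts, and a transcript was counted at a fold of 2 or more. With 1 library per group no test was run, and p-values are only those of the authors' deposited table. Folds of single transcripts are ratios of reads divided by size factors, without the added 1, with an exact (Clopper-Pearson) 95% interval for the split of the reads between the libraries. Shares of reads have 95% Wilson intervals. Counting error was simulated by drawing Poisson reads for both libraries from 1 shared level.

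The steps were tested on simulated data for spongy against healthy fruit at 5 days, with 29449 transcripts of which 200 had a known fold. The simulated reads came back equal in 100% of values. A simulated fold of 2 gave a median log2 ratio of 1.00 and 51% of its transcripts were counted, a fold of 4 gave 2.00 and 100%, and 0.178% of the unchanged transcripts were counted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

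Before the data were examined, 26 lists of gene functions were fixed, to be matched by gene description. The files do not pair the transcripts with names. Of the 30582 transcript numbers, 0 matched the table of 38372 mango genes of assembly CATAS_Mindica_2.1, and 0 members of the lists were found, so no list is reported. The rule for naming single transcripts, also fixed beforehand, allowed at most 2 higher and 2 lower per comparison where no descriptions exist. They were those with the highest and lowest log2 ratio in the upper part of the compared transcripts, above their median level. At most 1 transcript per locus was taken, in place of 1 per description. Loci 2, 3 and 5547 were singled out after their values were seen.

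The alternatives fixed beforehand were an added value of 0.5 or 10, no level minimum or a minimum of 50, log2 ratios centred on their median, the same total per library, TMM factors (30% of ratios and 5% of levels trimmed) and the authors' adjusted p. Chosen after the data were seen were transcripts summed by locus, leaving out loci 2 and 3, the same total outside those loci, the first loci up to the first breakpoint alone, and reads thinned at random to the size factor of the shallowest library, 0.389. Breakpoints along the locus numbers were found by splitting the loci 4 times where the median log2 ratios of 3 comparisons differed most between the sides, with at least 50 loci on each side.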

Results

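Spongy tissue is a ripening disorder of Alphonso mango in which part of the flesh turns soft, pale and corky while the outside of the fruit looks sound. RNA from the mesocarp, the edible flesh, was sequenced from healthy and from spongy fruit at 2 ripening stages, 5 days after harvest (table green) and 10 days after harvest (mid ripe). Each of the 4 groups held 1 library, so none of the differences below has a replicate check, and no test between groups was made. The files list 30582 assembled transcripts of 14276 loci under assembly numbers and do not pair them with gene names, so transcripts are given by those numbers. Each number names the locus, the transcript within it and the length. The recovered reads came to 52778919 in healthy fruit at 5 days, 75039464 in healthy fruit at 10 days, 62356287 in spongy fruit at 5 days and 56590748 in spongy fruit at 10 days. Intervals given with folds and shares are 95% intervals that cover counting error only, and reads were not counted as molecules.

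A single locus, locus 2, took most of the reads in 3 of the 4 libraries. Its 180 listed transcripts held 21.6% of the recovered reads in healthy fruit at 5 days and 72.3% at 10 days. The Wilson intervals were 0.0222 and 0.0203 percentage points wide. The assembly numbers count more transcripts in loci 2 and 3 than are listed, so shares are of the listed transcripts only. How a read that matches several transcripts of a locus was counted is not given. If it was counted for each, the shares and totals are inflated and the intervals too narrow. In spongy fruit the share was 51.3% at 5 days and 51.0% at 10 days. Locus 3, with 649 listed transcripts, took 25.4% in healthy fruit at 5 days, 14.7% in healthy fruit at 10 days, 15.6% in spongy fruit at 5 days and 14.7% in spongy fruit at 10 days. Locus 5547, a single transcript of 364 nt, was likewise lowest in healthy fruit at 5 days and highest in healthy fruit at 10 days, with 0.468%, 3.68%, 1.28% and 1.33% of the reads in the same order of libraries. These 3 loci had the highest shares of any locus and were singled out after their values were seen. Outside loci 2 and 3 the healthy library of 10 days kept 9792433 reads, against 27966100, 20654390 and 19393764 in healthy fruit at 5 days, spongy fruit at 5 days and spongy fruit at 10 days. The median transcript had 248 reads in healthy fruit at 5 days and 51 in healthy fruit at 10 days, and 196 and 173 in spongy fruit at 5 and 10 days. Comparisons with healthy fruit at 10 days are therefore the least precise.

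**Figure D1:**
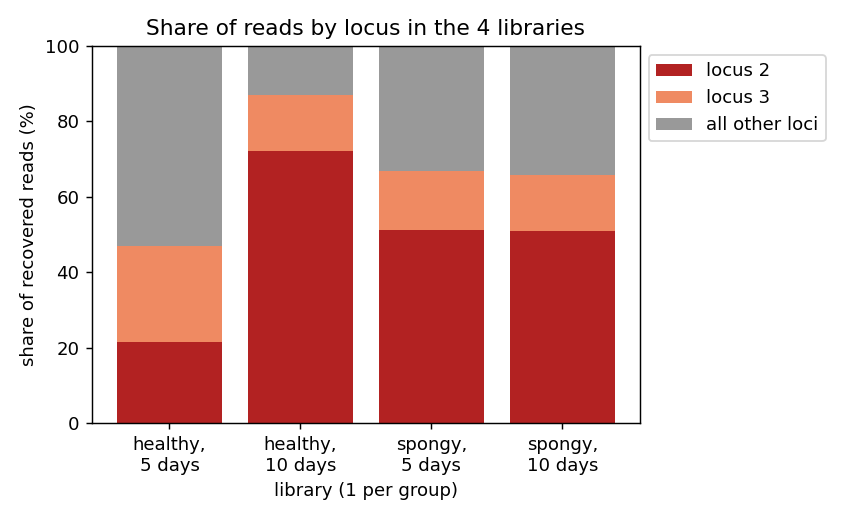
Stacked bars give the share of recovered reads (%, y axis) of locus 2, locus 3 and all other loci in each library (x axis, 1 library per group). Locus 2 took 21.6% in healthy fruit at 5 days and 72.3% at 10 days, and 51.3% and 51.0% in spongy fruit.

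The first comparison asked which transcripts differed between spongy and healthy flesh at the earlier stage. Of 29316 transcripts compared at 5 days, 4309 were at least 2-fold higher and 2772 at least 2-fold lower in spongy fruit. At least 4-fold higher were 2000 transcripts and at least 4-fold lower 487. The transcripts of locus 2 were higher in spongy fruit, by a median log2 ratio of 1.86, with 149 of 175 compared at least 2-fold higher and 2 lower, and the median was 1.08 with the same total per library. Those of locus 3 were mostly alike, with 588 of 636 within 2-fold. Locus_5565_Transcript_23_25_Confidence_0.615_Length_1417 had 21839 reads in spongy and 10 in healthy fruit, a normalized level 3166-fold higher (1721 to 6604). Locus_14442_Transcript_1_1_Confidence_1.000_Length_215 had 3582 reads against 1, a ratio of 5193 (931 to 205179). In the other direction, Locus_11482_Transcript_2_2_Confidence_0.000_Length_1764 had 10 reads in spongy and 1497 in healthy fruit and was 103-fold lower (56.0 to 216). Locus_11863_Transcript_1_1_Confidence_0.000_Length_591 was 34.6-fold lower (22.5 to 56.2), with 21 reads against 1054.

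Reads drawn from 1 shared level for both libraries, so that only counting error remained, put 55 transcripts at least 2-fold apart at 5 days. In the authors' deposited table, made with DESeq2, 0 of 30577 transcripts with a p-value had an adjusted p under 0.05, 532 had an unadjusted p under 0.05, and the smallest adjusted p was 0.980. The unadjusted count was under a share of 0.05 of the transcripts, here and in the other comparisons, so it marks no excess. With 1 library per group the authors' test had no replicates, so 0 at an adjusted p does not show likeness. The direction of the split depended on the scaling. With every library set to the same total the median log2 ratio of all transcripts was -0.77, and 2430 transcripts (18.4% of those 2-fold apart) were higher and 10774 lower, against 60.9% higher under the authors' scaling. The 4-fold counts turned as well, to 1315 higher and 2029 lower. With TMM factors 4272 were at least 2-fold higher and 2821 lower. With the same total outside loci 2 and 3 the median was -0.09, with 3993 (53.9%) higher and 3419 lower. At 4-fold that last scaling gave 1919 higher and 626 lower.

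At 10 days the same comparison gave more differences. Of 29059 transcripts compared, 5183 were at least 2-fold higher and 3461 at least 2-fold lower in spongy fruit, and 2520 and 748 were at least 4-fold higher and lower. Locus 2 lay on the other side of its position at 5 days, with a median log2 ratio of -2.11. Of its 180 compared transcripts, 144 were at least 2-fold lower in spongy fruit and 14 at least 2-fold higher. With the same total per library that median was -0.19, still below 0. Locus_14440_Transcript_1_1_Confidence_1.000_Length_280 had 27633 reads in spongy and 1 in healthy fruit, a ratio of 9693 (1740 to 382876). It had 43894 reads in spongy and 70 in healthy fruit at 5 days. Locus_5603_Transcript_15_16_Confidence_0.193_Length_1848 was higher in spongy fruit by a log2 ratio of 9.92 (interval 559-fold to 2003-fold), with 31359 reads against 11, and had 7 reads in each library of 5 days. Locus_3_Transcript_1621_2381_Confidence_0.006_Length_1494 was 289.8-fold lower in spongy fruit (272 to 309), with 972 reads against 98807. Locus_13725_Transcript_2_3_Confidence_0.960_Length_457 was 158-fold lower (132 to 190.5), with 124 reads against 6880. The log2 ratios of these single transcripts, in order, were 12.8, 9.92, -8.18 and -7.29. With the same total per library they were 14.0, 11.7, -6.26 and -5.38.

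Counting error alone put 522 transcripts at least 2-fold apart at 10 days. The authors' deposited table, from DESeq2, held 0 transcripts with an adjusted p under 0.05 and 668 with an unadjusted p under 0.05, and its smallest adjusted p was 0.827. With the same total per library the median log2 ratio of all transcripts was 1.92, and 24519 transcripts (99.4%) were higher and 153 lower, against 59.96% higher under the authors' scaling. With the same total outside loci 2 and 3 the median was 0.54, with 8848 (86.3%) higher and 1399 lower. At 4-fold the counts were 13078 and 82 with the same total per library, and 3599 and 321 with the same total outside loci 2 and 3.

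Under the authors' scaling many of the differences between spongy and healthy fruit had the same direction at both stages. Across the 29539 transcripts with a mean of at least 10 over all 4 libraries, the log2 ratio at 5 days and that at 10 days, which share no library, had a Pearson correlation of 0.62 and a Spearman correlation of 0.55. Of these transcripts 2870 were at least 2-fold higher in spongy fruit at both stages, where independent lists of the same sizes would share 795, and 1291 were lower at both, where independent lists would share 330.3. Opposite directions were found for 300 transcripts higher at 5 and lower at 10 days and 118 lower at 5 and higher at 10 days. Both counts were below the 534 and 492 of independent lists. These 2-fold counts were taken under the authors' scaling only. With the same total per library 2430 transcripts were higher and 10774 lower at 5 days, and 24519 higher and 153 lower at 10 days. All of these shared and opposite counts therefore depend on the scaling. Under the authors' scaling 654 transcripts of 501 loci were at least 8-fold higher at both stages, and 7 were at least 8-fold lower at both. These counts were 631 and 3 with the same total per library, and 727 and 4 with the same total outside loci 2 and 3. The 654 took 0.161% and 0.0134% of the reads of healthy fruit at 5 and 10 days, and 1.90% and 2.04% of those of spongy fruit. Of the 654, 102 lay in loci 1 to 5547, which hold 18812 of the 30582 transcripts. Another 238 lay in loci 5548 to 6344 and 289 in loci 6345 to 11178, which hold 1515 and 6982. These ranges, described below, were set on the same ratios. Transcripts are not independent replicates, so these correlations, 2 in all with the one for ripening, carry no p-value.

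**Figure D2:**
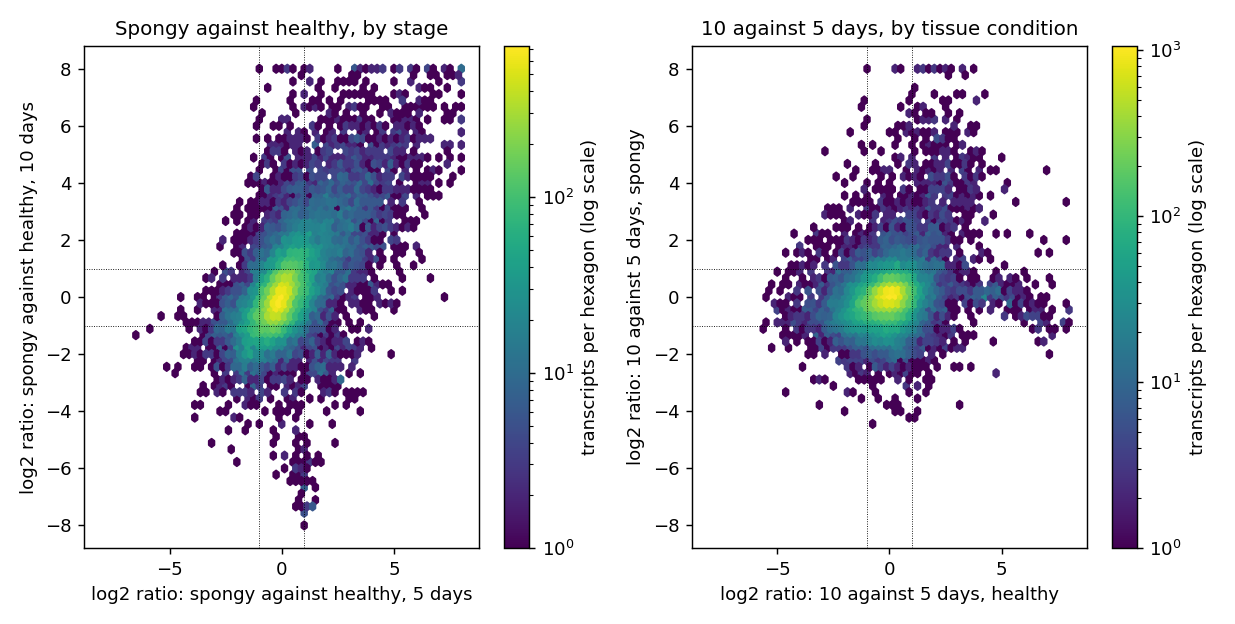
Hexagons give the number of transcripts (log colour scale) by log2 ratio on both axes, on the left for spongy against healthy fruit at 5 days (x) and 10 days (y), on the right for 10 against 5 days in healthy (x) and spongy fruit (y). Dotted lines mark 2-fold and values beyond the axis ends are drawn at the ends; the Pearson correlation was 0.62 on the left and 0.26 on the right.

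Differences between the ripening stages in healthy fruit came next. Of 28528 transcripts compared, 2273 were at least 2-fold higher and 3178 at least 2-fold lower at 10 than at 5 days. At least 4-fold higher were 697 and lower 704, but 463 and 700 without loci 2 and 3. The transcripts of locus 2 were higher at 10 days by a median log2 ratio of 4.28, with 157 of 177 at least 2-fold higher and 1 lower, and the median was 1.53 with the same total per library. Locus_14294_Transcript_1_1_Confidence_1.000_Length_463 was 314-fold higher at 10 days (291 to 339), with 45024 reads against 677. Locus_1654_Transcript_1_1_Confidence_0.000_Length_1070 was 347-fold higher (175 to 807), with 588 reads against 8. Locus_7202_Transcript_2_2_Confidence_0.000_Length_1245 was 48.8-fold lower at 10 days (26.5 to 102), with 10 reads against 2305. Locus_6272_Transcript_1_1_Confidence_0.000_Length_2568 was 34.8-fold lower (22.0 to 58.8), with 18 reads against 2958. The log2 ratios of these single transcripts, in order, were 8.29, 8.14, -5.56 and -5.09. With the same total per library they were 5.55, 5.55, -8.19 and -7.77, so the folds depend on the scaling beyond their intervals.

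Counting error alone put 422 transcripts at least 2-fold apart in healthy fruit. In the authors' deposited table, from DESeq2, 0 transcripts had an adjusted p under 0.05 and 408 an unadjusted p under 0.05. With the same total per library the median log2 ratio of all transcripts was -2.72, and 288 transcripts (1.01%) were higher and 28103 lower, against 41.7% higher under the authors' scaling. At 4-fold that scaling gave 163 higher and 24990 lower. With the same total outside loci 2 and 3 the median was -0.73, with 841 (7.90%) higher and 9810 lower, and at 4-fold 421 and 2182.

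In spongy fruit fewer transcripts differed between the stages. Of 29193 compared, 1798 were at least 2-fold higher and 1768 at least 2-fold lower at 10 than at 5 days, and 771 and 204 were at least 4-fold higher and lower. Most of locus 2 stood nearly level, with a median log2 ratio of 0.10 and 159 of 179 transcripts within 2-fold. Of the others, 19 were at least 2-fold higher at 10 days and 1 lower. Locus_5603_Transcript_15_16_Confidence_0.193_Length_1848 was 5116-fold higher at 10 days (2483 to 12727), with 31359 reads against 7. Locus_5549_Transcript_1_2_Confidence_0.333_Length_2053 was 2608-fold higher (1198 to 7107), with 13700 reads against 6, and had 8 reads in each healthy library. Locus_13755_Transcript_1_1_Confidence_0.000_Length_2449 was 18.1-fold lower at 10 days (12.8 to 26.4), with 34 reads against 703. Locus_11068_Transcript_4_6_Confidence_0.333_Length_943 was 8.15-fold lower (6.06 to 11.2), with 49 reads against 456.

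Counting error alone put 91 transcripts at least 2-fold apart in spongy fruit. In the authors' deposited table, from DESeq2, 0 transcripts had an adjusted p under 0.05 and 124 an unadjusted p under 0.05. The counts at 2-fold were nearly balanced, and their direction depended on the setting. They were 1808 higher and 1757 lower with TMM (trimmed mean of M values) scaling, 1721 and 2057 with the same total per library, and 1589 and 2244 with the same total outside loci 2 and 3, where the median was -0.10. With 10 in place of 1 added to each level they were 1463 and 1042, and with a mean of at least 50 they were 1126 and 721. Without a minimum they were 1925 and 2137, and with reads thinned to 1 depth 2102 and 2163. Summed by locus they were 1103 and 865, and in loci 1 to 5547 alone 596 and 682. At 4-fold 33 were lower with 10 added and 56 with a mean of at least 50, against 584 and 496 higher. The difference between the healthy and the spongy count of transcripts was not tested.

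The ripening differences of healthy and spongy fruit were only weakly correlated. The log2 ratios of 10 against 5 days had a Pearson correlation of 0.26 and a Spearman correlation of 0.23 across the 29539 transcripts. At least 2-fold higher at 10 days in both were 741 transcripts, where independent lists would share 159, and 498 were lower in both, where independent lists would share 214. Opposite directions were found for 191 transcripts higher in healthy and lower in spongy fruit and for 199 lower in healthy and higher in spongy fruit, near the 167 and 204 of independent lists. These counts were taken under the authors' scaling only and depend on it. With the same total per library 288 transcripts were at least 2-fold higher and 28103 lower at 10 days in healthy fruit.

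The ratio of spongy to healthy fruit changed along the locus numbers of the assembly, in steps and in drifts between them. In loci 1 to 5547 the median log2 ratio was -0.09 over 18534 compared transcripts at 5 days and -0.12 over 18432 at 10 days. In loci 5548 to 6344 it was 0.68 over 1418 and 1.31 over 1485, and in loci 6345 to 11178 it was 0.31 over 6443 and 0.45 over 6789. In loci 11179 to 13713 it was -0.38 over 2422 and -0.62 over 1991. In loci 13714 to 14473 it was 1.95 over 499 at 5 days and 0.31 over 362 at 10 days. Along these ranges the median transcript length fell, 1286, 1056, 838, 361 and 279 nt. The median normalized level fell too, 323, 144, 76.7, 20.3 and 16.8. The last ranges thus lie near the level minimum of 10, and the transcripts compared there differ between the stages. Length and level were not separated from position. Loci 1 to 5547 alone had 1586 transcripts at least 2-fold higher and 1886 lower in spongy fruit at 5 days, and 1841 higher and 2451 lower at 10 days, so that the direction of the split at 2-fold turned at both stages. At 4-fold these loci had more higher than lower transcripts, 561 against 286 at 5 days and 609 against 514 at 10 days. The 4 breakpoints were set on these ratios after the values were seen. The first had a gain of 2720 in the sum of squares between its sides, on standardized ratios, against at most 38.9 for the best split in 100 shuffles of the loci.

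**Figure D3:**
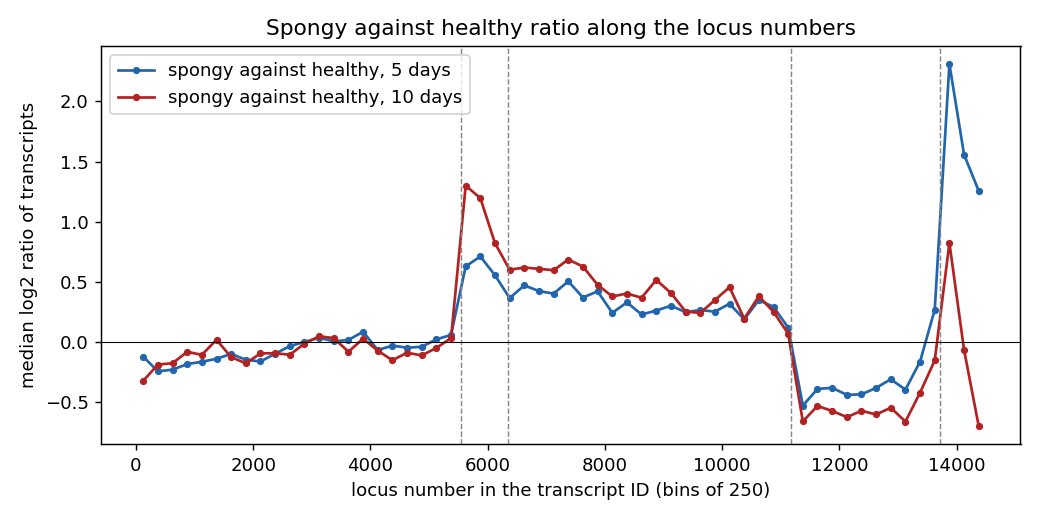
Points give the median log2 ratio of spongy against healthy fruit (y axis) of the transcripts in bins of 250 locus numbers (x axis) at 5 days and 10 days, and dashed lines mark the 4 breakpoints. The medians over loci 5548 to 6344 were 0.68 at 5 days and 1.31 at 10 days, those over loci 11179 to 13713 were -0.38 and -0.62, and those over loci 13714 to 14473 were 1.95 and 0.31.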

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

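The test on the SD within locus 2 was set before its result, and the look at its quartiles was chosen only after the result was seen.

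Locus 2 stood out because its ratio of spongy to healthy fruit had opposite signs at the stages, with a median log2 ratio of 1.86 at 5 days and -2.11 at 10 days. With the same total per library these medians were 1.08 and -0.19, the latter near 0. The difference between the stages was not tested, since each value rests on 1 library per group. Opposite signs set apart 300 transcripts of 124 loci, at least 2-fold higher in spongy fruit at 5 days and lower at 10 days. Another 118 had the reverse order, and neither count was tested. Independent lists of the same sizes would hold 534 and 492, so both counts were below those. The 300 include transcripts of locus 2, so they are not an observation separate from it. Both counts were taken under the authors' scaling and depend on it. With the same total per library 153 transcripts were at least 2-fold lower at 10 days, and 10774 at 5 days. The 300 took 22.2% of the reads of healthy fruit at 5 days, 79.7% of those at 10 days, and 54.1% and 54.0% of those of spongy fruit. Locus 2 as a whole took 21.6%, 72.3%, 51.3% and 51.0% in the same order. The 118 took 0.146% and 0.00486% in healthy and 0.0370% and 0.0686% in spongy fruit.

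Locus 2 took a higher share of reads in healthy fruit at 10 than at 5 days, 72.3% against 21.6%, and no size factor enters a share. A single RNA present in a larger amount would move the transcripts of the locus by about the same factor. The 155 transcripts of the locus with at least 100 reads in every library had an SD of 1.33 in their log2 ratio of 10 against 5 days, above the limit of 1 set beforehand. Their quartiles were 3.85 and 4.85, which corresponds to an SD of 0.74, so the SD is carried by the tails, and whether 1 RNA source accounts for most of them cannot be told. Also open are what locus 2 is, since the files do not pair it with a name, whether library preparation or fruit differed in that 1 library, and a difference between the stages of healthy fruit, which was not tested.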

How the results depend on the processing

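The locus sums, the removal of loci 2 and 3, the total outside them, the thinning and the first loci alone were chosen after seeing the data, as were all alternatives for locus 2, for single transcripts, for the counts at both stages and for the correlation between stages; the others were fixed before. Main counts of transcripts at least 2-fold apart were 7081 (spongy against healthy, 5 days), 8644 (10 days), 5451 (stages, healthy) and 3566 (stages, spongy). With the same total per library they were 13204, 24672 and 28391 for the first 3. With the total outside loci 2 and 3 the healthy stages gave 10651. Fewer values were compared with a mean of at least 50, which gave 4645 at 5 days and 3360 and 1847 for the healthy and spongy stages. Summed by locus the counts were 3273, 4053, 2464 and 1968, and in loci 1 to 5547 alone 3472, 4292, 2909 and 1278, again with fewer values compared. The authors' deposited table, from DESeq2, gave 0 in each comparison at an adjusted p of 0.05, against 532, 668, 408 and 124 at an unadjusted p of 0.05. Each of the latter is under a share of 0.05 of the transcripts. Other alternatives for these counts stayed within 1.5 times the main count. The median log2 ratio of locus 2 between the healthy stages was 1.53 with the same total per library. The sign of the locus 2 median held in every comparison under each scaling run, but some medians were near 0. For spongy against healthy fruit at 10 days it was -0.19 with the same total per library. For the spongy stages it was 0.0023 with the same total outside loci 2 and 3. The correlation for ripening stayed between 0.22 and 0.30, and that between stages between 0.50 and 0.67. Of the alternative values of single named transcripts, 32 lay within the counting interval, 16 outside it, and 0 changed sign. The causes of these shifts were not tested further. Summing by description and the gene lists could not be run without descriptions. A fit of condition and stage together, which pairs spongy with healthy fruit by stage and leaves 1 residual degree of freedom, was not run. Depth limits healthy fruit at 10 days most, with a median of 51 reads per transcript.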

Other observations

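The tests on scaling and on the make-up of the transcript reference were chosen only after their results were seen in part, and the tests on depth and on a source of fixed make-up were set before theirs.

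A set of 245 transcripts from 197 loci stood apart in spongy fruit at 10 days, at least 8-fold higher than in spongy fruit at 5 days and than in healthy fruit at 10 days. Their median was 396 reads there, against 13 in spongy fruit at 5 days and 6 and 4 in healthy fruit at 5 and 10 days. Of the 245, 107 were within 2-fold of each other in spongy and healthy fruit at 5 days. Their median there was 4 reads in spongy and 6 in healthy fruit, too few to show likeness. By position, 17 of the 245 lay in loci 1 to 5547, 106 in loci 5548 to 6344 and 122 in loci 6345 to 11178. Together the 245 took 0.637% of the reads of spongy fruit at 10 days and 0.0234% at 5 days. The matching set in healthy fruit at 10 days held 110 transcripts of 29 loci, with 66 of them from locus 3 and 14 from locus 2, and took 16.8% of the reads of that library against 2.07% at 5 days. Locus 3 thus held transcripts far higher in that library while 509 of its 640 compared transcripts were within 2-fold of healthy fruit at 5 days. Both sets were taken under the authors' scaling only, and the 110 depends on it. With the same total per library 70 transcripts, against 190, were at least 8-fold lower in spongy fruit at 10 days. Between the healthy stages 84, against 405, were at least 8-fold higher at 10 days. Under the authors' scaling 99 transcripts of 72 loci were at least 4-fold lower in spongy fruit at both stages, against 1339 of 978 loci at least 4-fold higher at both. The counts were 17 and 1257 with the same total per library, and 56 and 1495 with the same total outside loci 2 and 3.

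Under the authors' scaling more transcripts were at least 4-fold higher than lower in spongy fruit at both stages. Scaling stays open at both stages, since at 5 days the same total per library turned the ratio of higher to lower to 0.65, and at 10 days, where the lowest ratio was 3.32, none of the scalings run lowered the log2 ratios by over 0.1. With reads thinned to 1 depth the ratio was 3.32 at 5 days and 2.88 at 10 days, which argues against depth. A candidate explanation is a transcript reference that may have been built from libraries in turn; among the loci before the first breakpoint set on the other stage the ratio was 1.97 at 5 days and 1.19 at 10 days, and without loci 2 and 3 it was 1.67 and 1.74. A breakpoint placed where the ratios step lowers these values by construction, so the explanation is neither supported nor excluded, and a real excess in spongy flesh stays open too.

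Some transcripts were almost without reads in healthy fruit. Among those with a mean of at least 10, 144 had at most 3 reads in both healthy libraries together, and 0 had so few in both spongy libraries. Of the 144, 5 lay in loci 1 to 5547, which hold 18812 of the 30582 transcripts. With reads thinned to 1 depth the counts were 451 and 97, a ratio of 4.65, which argues against depth as the cause. RNA of another organism with a fixed make-up would keep its transcripts in 1 ratio between the stages. The SD of the log2 ratio of 10 against 5 days in spongy fruit over the 144 was 2.68. This argues against 1 such source for all of them, but the pooled SD cannot speak to a source of only some. Such a partial source, a source whose make-up differs between stages, the make-up of the reference and transcripts of the spongy flesh itself may each remain. Without sequences or names they were not tested.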
